A study of Mus musculus with 26 samples.

How the data were processed

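RNA was measured in 26 libraries of mouse cells, 2 for each of 13 groups: the R1-ESC line, 8 iPSC lines and the 4 kinds of cell they were made from. Per the labels' protocols, RNA was taken with TRIzol, mRNA was drawn with oligo(dT), and short fragments were primed with random hexamers and sequenced on an Illumina HiSeq. Reads were aligned with TopHat 1.3.3 to mouse build NCBIM37 (mm9), per the submitters' processing notes. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments, per the file headers, with 37157 loci and 1 estimate and a status per locus and library. The program that made the estimates, the annotation release, any scaling between libraries and the use of strand are not given in the sources used here. Of the loci, 37120 had the start and end of the same gene in GENCODE M1, which gave the gene types, and 16 gene IDs had several loci, which were kept apart.

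The library sums of FPKM are not depths. The estimates and the upper bounds of their intervals implied 12385562 to 15196607 fragments per library. The status was FAIL at 16 to 38 loci per library. Between 81 and 136 loci per library were listed at 0 while their replicate had at least 10 FPKM, with 0 to 5 protein-coding loci among them. No 2 libraries held the same values. The replicate numbers do not pair the samples: over 78 pairs of groups, differences between replicates had Pearson's r across loci of -0.0769 to 0.105.

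From FPKM, log2(FPKM + 1) was computed, a scale that understates the change of genes with low values. Loci with at least 1 FPKM in at least 2 libraries were tested, 19356 in all and 14904 of them protein-coding. Comparisons of cell types and single lines used limma 3.58.1 in R 4.3.3 with 13 group means (13 residual degrees of freedom), moderated variances with a trend, and Benjamini-Hochberg adjustment. A locus was called at an adjusted p under 0.05 with a log2 difference of at least 1 in size. Comparisons of lines of different origin, and the trend over the first number of the names (slope of at least 0.5), used 1 mean per line, since libraries of a line are not separate lines. Group means and SDs in the text are of FPKM, and log2 differences come from the fit. In total 39 gene lists were tested with limma's camera at an inter-gene correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison; 591 of 604 listed symbols were found. Sets of 200 loci that most distinguish 2 source cell types were tested in the lines. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared the values and figures.

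Genes were named by a rule: in each comparison up to 10 called genes with the largest rises and as many with the largest falls, with a symbol other than a clone or predicted-gene name, a group mean of at least 5 FPKM and no overlap between the libraries of the sides; up to 4 members of each list with the largest differences; and a fixed set of reprogramming, imprinted, sex-linked and DNA methylation genes. From these, genes were taken that kept their calls when single libraries were left out, a choice made after seeing the data, and the exceptions are stated. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except those named as chosen later.

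The tests were tried on 19356 simulated loci, 66 or 67 changed per size. In the comparisons at library level, the share of changed loci recovered was 73.1% to 92.5% at 1.5, 86.6% to 95.5% at 2 and 92.4% to 100% at 3 on the log2 scale, with 0 to 6 false calls per comparison. At line level the share at 1.5, 2 and 3 was 56.7%, 82.1% and 92.4% for all lines against R1-ESC, 67.2%, 74.6% and 90.9% for 3-APC against 2-APC lines and 67.2%, 79.1% and 84.8% for 2-HPC against 2-APC lines, with 1, 6 and 8 false calls. For the trend it was 56.7%, 85.1% and 92.4%, with 6 false calls, at slopes of 0.75, 1 and 1.5. In 2-HPC against 2-APC lines, 200 simulated loci moved by 0.2 gave unadjusted p = 1.9e-18 by limma's camera at its preset correlation. An unmoved set gave 0.89, and 1 set gives no error rate.

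Alternatives were a pseudocount of 0.1, no filter, quantile normalization, median ratio scaling, no minimum difference, the replicate number as a block, a fit on the compared groups alone, loci without an OK status left out, the line as a random effect, sets of other sizes, and each library or line left out in turn. Each fit assumes 1 spread per locus for all its groups, also for a group left with 1 library. P-values of noisier groups may thus be too small. Of the intervals of the estimates, the upper bounds served only for the fragment numbers per library. The remaining columns were not used here, and no reads were analysed here.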

Results

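RNA was sequenced from 13 kinds of mouse cell with 2 libraries each, 26 libraries in all. R1-ESC is a mouse embryonic stem cell line of strain 129 and is the pluripotent reference. The 8 iPSC lines, which are somatic cells returned to a pluripotent state by transcription factors, came from strain 129-M2rtTA, which carries a doxycycline-responsive activator. The lines 1-MEF-iPSC-37 and 1-MEF-iPSC-42 were made from embryonic fibroblasts (1-MEF), 2-APC-iPSC-32 and 2-APC-iPSC-4 from adipose progenitor cells (2-APC), 2-HPC-iPSC-16 and 2-HPC-iPSC-18 from haematopoietic progenitor cells (2-HPC), and 3-APC-iPSC-3 and 3-APC-iPSC-9 from other adipose progenitor cells (3-APC). The series is titled as one of sequential reprogramming, and the first number of each name was read as the round of reprogramming, which the labels do not state. FPKM values summed to between 1416240 and 2069693 per library. Pearson's r between the replicates of a group, across 19356 loci, ran from 0.928 in 2-APC to 0.969 in 2-APC-iPSC-32; it is across genes, which are not independent replicates. The SD of the log2 difference between replicates was 0.917 in 2-APC and 0.886 in 1-MEF-iPSC-42, and at most 0.732 in the other groups. R1-ESC was at passage 20 to 22, the iPSC lines at 10 to 12 and the source cells at 0 to 1. For lines against R1-ESC or their source, passage cannot be separated from the kind of cell, nor strain against R1-ESC. Nothing in the labels says that the replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

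The lines made from embryonic fibroblasts were compared with those fibroblasts. Pou5f1, the transcription factor at the centre of the pluripotency network (ENSMUSG00000024406, chromosome 17, 35642982 to 35647721 on mouse build NCBIM37, mm9), averaged 1299 ± 102 FPKM in the lines and 0.207 ± 0.293 in 1-MEF cells (SD, n = 4 and 2), a log2 difference of 10.09 (SE 0.10, adjusted p = 3.4e-18). Dppa5a, L1td1, Utf1, Tdgf1, Sall4 and Nanog, all markers of embryonic stem cells, rose with log2 differences of 9.14, 8.67, 8.52, 8.32, 7.91 and 7.79 (SE at most 0.27, adjusted p at most 3.0e-13). Among the largest falls, cardiac actin Actc1 averaged 2.18 ± 1.16 FPKM against 469 ± 7.37 (SD, n = 4 and 2), and the troponins Tnni1, Tnnt2 and Tnnc1 had log2 differences of -6.93, -6.80 and -6.59 (SE at most 0.39, adjusted p at most 6.6e-10). The matrix gene Mgp, the growth factor gene Ptn and the imprinted RNA H19 fell with log2 differences of -6.57, -6.89 and -6.36, and the imprinted growth factor Igf2 averaged 54.9 ± 30.2 FPKM against 3375 ± 145 (SD, n = 4 and 2).

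For each gene list fixed beforehand, the median is that of its members' log2 differences. Of the pluripotency factors, 18 rose and 0 fell among 18 (18 and 0 adjusted over the list alone), with a median of 6.83 (camera adjusted p = 4.8e-17, 3.4e-04 with an estimated correlation). Among Hox genes, which hold positional identity, 0 rose and 29 fell among 32 (0 and 29 adjusted over the list alone), with a median of -2.39 (camera adjusted p = 2.2e-14, 0.031 with an estimated correlation). In the list of fibroblast and mesenchymal genes, 0 rose and 24 fell among 26 (0 and 24 adjusted over the list alone), with a median of -2.94 (camera adjusted p = 1.1e-07, 0.38 with an estimated correlation). Here limma called 6537 of 19356 loci, 3226 higher and 3311 lower in the lines, of which 5505 were protein-coding.

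The 2-APC lines against their adipose progenitors gave the highest count of the source comparisons. Pou5f1 averaged 1410.3 ± 178 FPKM in the lines and 0.0101 ± 0.0143 in 2-APC cells (SD, n = 4 and 2), a log2 difference of 10.44 (SE 0.10, adjusted p = 2.1e-18). L1td1, Dppa5a, Sall4, Utf1 and Tdgf1 averaged 568, 536, 462, 403 and 265 FPKM in the lines and were listed at 0 in both 2-APC libraries. The collagen genes Col3a1, Col1a2 and Col1a1 and the matrix genes Postn and Thbs2 fell with log2 differences of -8.40, -7.18, -6.98, -7.38 and -7.26 (SE at most 0.80, adjusted p at most 6.2e-07). The largest fall was that of Lyz2, the lysozyme of macrophages, at 1.399 ± 2.57 FPKM against 1035 ± 1204 (SD, n = 4 and 2). The adipocyte genes Fabp4, a fatty acid carrier, and Lpl, a lipase, averaged 0.106 ± 0.212 FPKM against 130.2 ± 145 (SD, n = 4 and 2) and 2.64 ± 1.07 FPKM against 239.7 ± 204 (SD, n = 4 and 2).

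For fibroblast and mesenchymal genes, 0 rose and 26 fell among 26 (0 and 26 adjusted over the list alone), with a median of -4.76 (camera adjusted p = 3.6e-10, 0.29 with an estimated correlation). For macrophage genes, 0 rose and 11 fell among 11 (0 and 11 adjusted over the list alone), with a median of -3.21 (camera adjusted p = 1.3e-04, 0.41 with an estimated correlation), with C1qb at 0.0519 ± 0.104 FPKM against 137 ± 147 (SD, n = 4 and 2). Within the adipose list, 2 rose and 9 fell among 11 (2 and 9 adjusted over the list alone), with a median of -2.66 (camera adjusted p = 0.0060, 0.47 with an estimated correlation). Replication and mitosis genes were higher, as 21 rose and 0 fell among 23 (21 and 0 adjusted over the list alone), with a median of 2.097 (camera adjusted p = 1.2e-08, 0.22 with an estimated correlation). The test called 8174 of 19356 loci with limma, 4366 higher and 3808 lower, 6913 of them protein-coding. In the macrophage list the median was -1.98 and -4.88 without replicates 1 and 2 of 2-APC.

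The 2-HPC lines were set against bone marrow progenitors. S100a9 and S100a8, which form the calprotectin of neutrophils, averaged 0.0371 ± 0.0741 FPKM against 39208 ± 2947 (SD, n = 4 and 2) and 0.0570 ± 0.114 FPKM against 14921 ± 2515 (SD, n = 4 and 2). The granule genes Ngp, Mpo and Camp fell with log2 differences of -12.91, -12.46 and -12.24 (SE at most 0.32, adjusted p at most 2.1e-14), and the neutrophil elastase Elane was listed at 0 in all 4 line libraries and averaged 5288 ± 510.0 FPKM (SD, n = 2) in 2-HPC cells. The haemoglobin genes Hba-a1 and Hba-a2 had log2 differences of -10.69 and -10.48 (SE at most 0.18, adjusted p at most 4.5e-17). Pou5f1, L1td1, Dppa5a and the matrix gene Sparc rose with log2 differences of 10.14, 8.76, 8.54 and 8.38 (SE at most 0.27, adjusted p at most 1.8e-13).

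Of the granulocyte and monocyte genes, 0 rose and 15 fell among 16 (0 and 15 adjusted over the list alone), with a median of -10.28 (camera adjusted p = 7.8e-12, 0.028 with an estimated correlation). Every erythroid gene moved the same way: 0 rose and 15 fell among 15 (0 and 15 adjusted over the list alone), with a median of -5.87 (camera adjusted p = 8.4e-13, 9.8e-04 with an estimated correlation). Among blood progenitor genes, 1 rose and 18 fell among 21 (1 and 18 adjusted over the list alone), with a median of -4.07 (camera adjusted p = 1.5e-07, 0.045 with an estimated correlation), with the myeloid regulator Sfpi1 (PU.1) at 0.754 ± 0.336 FPKM against 249.7 ± 6.26 (SD, n = 4 and 2). Paternally expressed imprinted genes were higher in the lines, where 17 rose and 0 fell among 23 (17 and 0 adjusted over the list alone), with a median of 3.26 (camera adjusted p = 6.5e-07, 0.028 with an estimated correlation), and Peg10 averaged 127 ± 47.4 FPKM against 0.266 ± 0.0955 (SD, n = 4 and 2). The fibroblast list was higher in the lines: 22 rose and 1 fell among 26 (23 and 1 adjusted over the list alone), with a median of 3.805 (camera adjusted p = 2.7e-06, 0.35 with an estimated correlation). Of the Y-linked genes, 3 rose and 0 fell among 4 (3 and 0 adjusted over the list alone), with a median of 2.03 (camera adjusted p = 0.018, 0.30 with an estimated correlation), and Eif2s3y averaged 17.6 ± 2.24 FPKM (SD, n = 4) in the lines and was listed at 0 in both libraries in 2-HPC cells. In total 7631 of 19356 loci were called by limma, 4032 higher and 3599 lower, including 6282 protein-coding loci.

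The 3-APC lines were set against 3-APC cells. Pou5f1 averaged 1264 ± 49.9 FPKM in the lines and 0.0440 ± 0.0622 in the progenitors (SD, n = 4 and 2), and L1td1, Utf1, Sall4 and Upp1, a uridine phosphorylase, rose with log2 differences of 8.90, 8.63, 8.61 and 7.76 (SE at most 0.23, adjusted p at most 2.3e-13). The matricellular gene Postn averaged 30.8 ± 13.2 FPKM against 2879 ± 98.7 (SD, n = 4 and 2), and Ptn, Mfap5, Tnmd and Col3a1 fell with log2 differences of -6.61, -6.19, -6.02 and -5.79 (SE at most 0.82, adjusted p at most 3.2e-06). Of the epithelial genes, 16 rose and 0 fell among 16 (16 and 0 adjusted over the list alone), with a median of 4.61 (camera adjusted p = 2.4e-08, 0.14 with an estimated correlation). Of the fibroblast and mesenchymal genes, 0 rose and 24 fell among 26 (0 and 25 adjusted over the list alone), with a median of -3.52 (camera adjusted p = 1.4e-09, 0.34 with an estimated correlation). In limma 7346 of 19356 loci passed, 4391 higher and 2955 lower, with 6181 protein-coding. The share of higher calls was 59.8%, and it was 48.1% after quantile normalization. The median log2 difference of all loci moved by -0.15 with quantile normalization and -0.14 with median ratio scaling.

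Each iPSC line was then compared with R1-ESC, to see how far the lines resembled embryonic stem cells. Here and in the later comparisons, the genes named as rising or falling kept their calls without any 1 library, except where stated. Across loci, Pearson's r with R1-ESC was 0.965 for 1-MEF-iPSC-37, 0.959 for 1-MEF-iPSC-42, 0.951 for 2-APC-iPSC-32 and 0.960 for 2-APC-iPSC-4. It was 0.956 for 2-HPC-iPSC-16, 0.964 for 2-HPC-iPSC-18, 0.964 for 3-APC-iPSC-3 and 0.963 for 3-APC-iPSC-9. The source cells were further away, at 0.826 for 1-MEF, 0.812 for 3-APC, 0.796 for 2-APC and 0.716 for 2-HPC. The cultures also differed in RNA of genes that fibroblasts hold at a high level. Over 167 protein-coding loci with at least 100 FPKM in 1-MEF cells, where they were at least 4-fold above the mean of the pluripotent groups, R1-ESC stood at a median of 14.9% and 15.8% of the 1-MEF level in its 2 libraries.

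**Figure D1:**
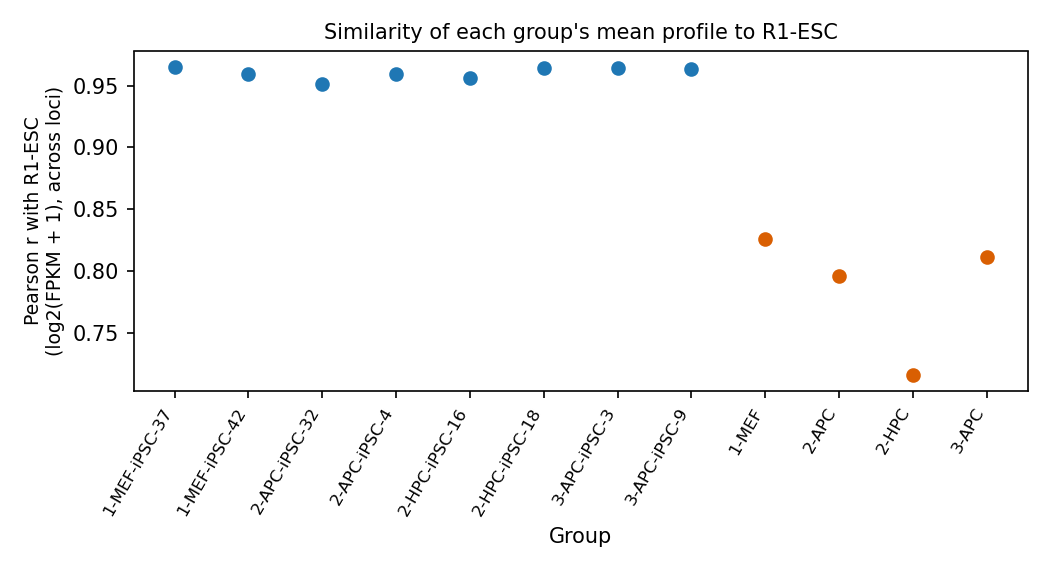
Pearson's r across loci between each group's mean log2(FPKM + 1) and that of R1-ESC, with 1 point per group. The 8 iPSC lines lie between 0.951 and 0.965, and the 4 source cell types between 0.716 and 0.826.

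**Figure D2:**
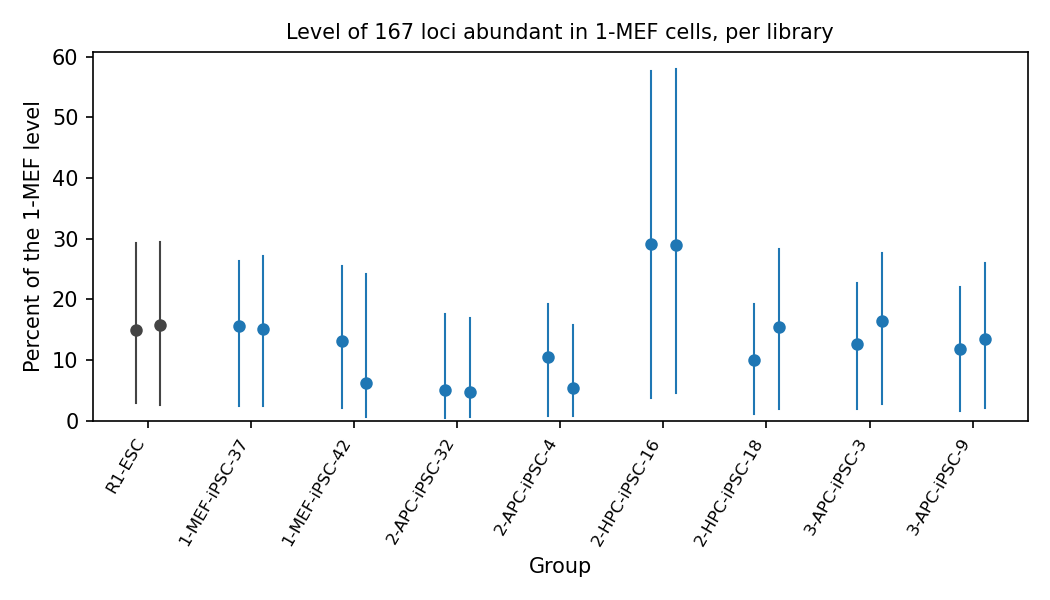
Level of the 167 loci high in fibroblasts, as a percent of their 1-MEF level, in each library of R1-ESC and the iPSC lines; points are medians and bars run from the 10th to the 90th percentile of the loci. Medians run from 4.80% in a 2-APC-iPSC-32 library to 29.1% in a 2-HPC-iPSC-16 library.

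In 1-MEF-iPSC-37, Apoa2, an apolipoprotein of high-density lipoprotein (ENSMUSG00000005681, chromosome 1, 173155185 to 173156510), averaged 36.2 ± 0.753 FPKM in the line and 0.801 ± 0.0240 in R1-ESC (SD, n = 2), a log2 difference of 4.37 (SE 0.28, adjusted p = 3.8e-07). The neural regulators Olig2 and Olig1 rose with log2 differences of 3.16 and 2.91 (SE at most 0.25, adjusted p at most 1.8e-05), from means of 0.0103 and 0.138 FPKM in R1-ESC. Dppa3, a maternal factor that guards DNA methylation in the zygote, averaged 57.5 ± 2.60 FPKM against 16.8 ± 1.12 (SD, n = 2), and the muscle enolase Eno3 17.7 ± 1.70 FPKM against 4.58 ± 1.08 (SD, n = 2). The iron-binding Lcn2, the opioid precursor Penk and the stress-induced Ier3 fell with log2 differences of -3.81, -3.52 and -1.89 (SE at most 0.39, adjusted p at most 0.0025). Of the 2-cell-stage genes, the Zscan4 family of the early embryo, 0 rose and 5 fell among 5 (0 and 5 adjusted over the list alone), with a median of -2.11 (camera adjusted p = 3.7e-11, 0.20 with an estimated correlation). These copies are near-identical, so reads may be split between them and single values are uncertain. The loci high in fibroblasts stood at a median of 15.6% and 15.2% of the 1-MEF level. By limma 240 loci were called, 63 higher and 177 lower. The count was 107 and 117 without replicates 1 and 2 of R1-ESC, 103 and 107 without replicates 1 and 2 of 1-MEF-iPSC-37, and 440 (121 higher) in a limma fit on the compared groups alone. Higher calls made up 26.2%, and 37.5% after quantile normalization.

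The sister line 1-MEF-iPSC-42 differed from R1-ESC in genes of the primed, post-implantation state: 0 rose and 8 fell among 13 (0 and 9 adjusted over the list alone), with a median of -1.23 (camera adjusted p = 2.5e-06, 0.19 with an estimated correlation). The DNA methyltransferase Dnmt3b averaged 44.1 ± 1.29 FPKM against 142 ± 9.38 (SD, n = 2), and the transcription factors Lef1 and Zic2, both on that list, and Pax6 of the neuroectoderm list fell with log2 differences of -2.82, -2.18 and -2.74 (SE at most 0.44, adjusted p at most 0.0012). Grhl2, an epithelial transcription factor, averaged 3.29 ± 0.582 FPKM against 17.4 ± 1.71 (SD, n = 2), and Dppa3 6.01 ± 1.75 FPKM against 16.8 ± 1.12 (SD, n = 2), both lower in the line. Apoa2, Olig1, Olig2 and the protease inhibitor Wfdc2 rose with log2 differences of 4.86, 3.19, 2.87 and 2.997 (SE at most 0.47, adjusted p at most 0.0011). The imprinted growth factor Igf2 averaged 30.1 ± 16.4 FPKM against 231 ± 6.68 (SD, n = 2). Of the fibroblast and mesenchymal genes 0 rose and 6 fell among 26 (0 and 12 adjusted over the list alone), with a median of -1.23 (camera adjusted p = 3.5e-07, 0.44 with an estimated correlation), while the loci high in fibroblasts stood at 13.2% and 6.30% of the 1-MEF level in its 2 libraries. Of the 2-cell-stage genes 0 rose and 5 fell among 5 (0 and 5 adjusted over the list alone), with a median of -2.91 (camera adjusted p = 9.8e-11, 0.19 with an estimated correlation). There were 591 limma calls, 201 higher and 390 lower. The count was 348 and 341 without replicates 1 and 2 of R1-ESC, 1733 without replicate 1 of 1-MEF-iPSC-42, and 1 in a limma fit on the compared groups alone, where no gene named here was called. For the fibroblast list the median was -1.92 without replicate 1 of 1-MEF-iPSC-42 and -0.55 without replicate 2 of 1-MEF-iPSC-42 (camera adjusted p = 0.10), with camera adjusted p from 5.8e-11 to 0.10 over its alternatives.

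2-APC-iPSC-32 had the most calls of the 8 lines against R1-ESC, most of them lower in the line. The matrix gene Dcn averaged 0.535 ± 0.117 FPKM against 157 ± 6.34 (SD, n = 2) and the chemokine Ccl2 4.04 ± 0.0652 FPKM against 335 ± 1.57 (SD, n = 2). Lum, Col6a1, Col3a1 and Col1a2 fell with log2 differences of -5.25, -4.78, -4.64 and -3.63 (SE at most 0.86, adjusted p at most 0.0027). Among fibroblast and mesenchymal genes 0 rose and 20 fell among 26 (0 and 21 adjusted over the list alone), with a median of -2.30 (camera adjusted p = 6.8e-11, 0.36 with an estimated correlation), where the loci high in fibroblasts stood at 5.06% and 4.80% of the 1-MEF level, the lowest of the lines. The glycolytic enzymes Pfkp and Hk1 and the pluripotency factor Zfp42 (Rex1) fell with log2 differences of -1.37, -1.36 and -1.17 (SE at most 0.26, adjusted p at most 0.0028). Apoa2, Olig1, Dppa3 and Eomes, a mesoderm regulator, rose with log2 differences of 4.18, 2.55, 2.03 and 1.85 (SE at most 0.38, adjusted p at most 0.0040). In the epithelial list 2 rose and 0 fell among 16 (4 and 0 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 8.5e-07, 0.27 with an estimated correlation). Dlk1, an imprinted Notch-family ligand, averaged 5.18 ± 0.480 FPKM against 113 ± 14.3 (SD, n = 2). The count by limma was 1229, 137 higher and 1092 lower, and 2007 with a pseudocount of 0.1. The share of higher calls was 11.2%, and it was 31.4% after quantile normalization. The median log2 difference of all loci moved by 0.12 with quantile normalization.

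In 2-APC-iPSC-4, Dlk1 averaged 8.85 ± 1.71 FPKM against 113 ± 14.3 (SD, n = 2), and its neighbour Meg3, a noncoding RNA of the maternal allele, fell with a log2 difference of -1.58 (SE 0.32, adjusted p = 0.0070). For the Dlk1-Dio3 cluster, whose genes are expressed from 1 parental allele, 0 rose and 3 fell among 6 (0 and 4 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 0.0022, 0.41 with an estimated correlation). The imprinted Igf2 averaged 25.5 ± 3.43 FPKM against 231 ± 6.68 (SD, n = 2), and Lcn2, Ier3 and Hk1 fell with log2 differences of -3.69, -2.51 and -1.60 (SE at most 0.39, adjusted p at most 0.0021). The primed-state list lay higher: 3 rose and 0 fell among 13 (3 and 0 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.0054, 0.46 with an estimated correlation). Apoa2, Olig1, Olig2 and the ribosome biogenesis gene Utp14a rose with log2 differences of 4.17, 2.43, 2.42 and 1.42 (SE at most 0.28, adjusted p at most 6.5e-05). In the fibroblast and mesenchymal list 0 rose and 10 fell among 26 (0 and 20 adjusted over the list alone), with a median of -1.49 (camera adjusted p = 6.3e-09, 0.50 with an estimated correlation), and the loci high in fibroblasts stood at 10.5% and 5.39% of the 1-MEF level. Calls by limma numbered 709, 84 higher and 625 lower, and 1095 with a pseudocount of 0.1. The count was 353 and 387 without replicates 1 and 2 of R1-ESC, 307 without replicate 2 of 2-APC-iPSC-4, and 81 (19 higher) in a limma fit on the compared groups alone, where of the genes named here only Apoa2, Igf2, Lcn2 and Utp14a stayed called. Dlk1 lost its call without R1-ESC replicate 1 (-3.40) and 2-APC-iPSC-4 replicate 2 (-3.36). Meg3 lost its call without R1-ESC replicate 1 (-1.58) and 2-APC-iPSC-4 replicate 2 (-1.38). The fibroblast median was -0.89 without replicate 2 of 2-APC-iPSC-4. Higher calls made up 11.8%, and 28.0% after quantile normalization.

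In 2-HPC-iPSC-16, Acta2, the smooth muscle actin, averaged 621 ± 3.14 FPKM against 48.6 ± 0.858 (SD, n = 2) in R1-ESC. The transgelin gene Tagln averaged 326 ± 0.927 FPKM against 32.3 ± 0.976 (SD, n = 2), and both are on the fibroblast list. Actg2, Myl9, Cnn1 and the intermediate filament gene Nes rose with log2 differences of 3.67, 3.66, 3.43 and 1.95 (SE at most 0.67, adjusted p at most 0.0033), as did the basement membrane collagens Col4a1 and Col4a2, by 1.59 and 1.55 on that scale. Of the Hox genes 8 rose and 0 fell among 32 (9 and 0 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 4.7e-14, 0.041 with an estimated correlation), with Hoxb6 at 3.29 ± 0.5261 FPKM against 0.571 ± 0.00986 (SD, n = 2). In the fibroblast and mesenchymal list 4 rose and 0 fell among 26 (8 and 1 adjusted over the list alone), with a median of 1.02 (camera adjusted p = 2.7e-05, 0.47 with an estimated correlation), and the loci high in fibroblasts stood at 29.1% and 29.0% of the 1-MEF level, the highest of the lines. Of the pluripotency factors 0 rose and 3 fell among 18 (0 and 3 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 2.6e-06, 0.024 with an estimated correlation), and Zfp42 averaged 60.2 ± 1.09 FPKM against 219.7 ± 8.35 (SD, n = 2). Of the mesoderm genes 3 rose and 0 fell among 9 (3 and 0 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 0.013, 0.38 with an estimated correlation). The glycolysis list had a median log2 difference of -0.52 (camera adjusted p = 4.5e-09, 0.024 with an estimated correlation), and Pfkp averaged 48.6 ± 0.224 FPKM against 175 ± 6.16 (SD, n = 2). The limma test called 748 loci, 355 higher and 393 lower. The count was 377 and 455 without replicates 1 and 2 of R1-ESC and 384 and 373 without replicates 1 and 2 of 2-HPC-iPSC-16.

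In its sister 2-HPC-iPSC-18, Olig1, Olig2 and Apoa2 rose with log2 differences of 2.75, 2.60 and 4.05 (SE at most 0.28, adjusted p at most 2.5e-05). The contractile Myl9 averaged 169 ± 27.4 FPKM against 30.7 ± 0.953 (SD, n = 2), Eno3 18.8 ± 1.07 FPKM against 4.58 ± 1.08 (SD, n = 2) and Dppa3 57.6 ± 14.9 FPKM against 16.8 ± 1.12 (SD, n = 2), all higher in the line. Penk, Lcn2, the growth factor Areg and Zfp42 fell with log2 differences of -3.65, -3.64, -2.86 and -1.18 (SE at most 0.39, adjusted p at most 0.0030). Among fibroblast and mesenchymal genes 1 rose and 2 fell among 26 (2 and 4 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 2.2e-04, 0.62 with an estimated correlation), and the loci high in fibroblasts stood at 10.05% and 15.5% of the 1-MEF level. A total of 274 loci passed in limma, 63 higher and 211 lower. The count was 133 and 117 without replicates 1 and 2 of R1-ESC, and 93 (28 higher) in a limma fit on the compared groups alone, where of the genes named here only Apoa2, Lcn2 and Olig1 stayed called. Myl9 lost its call without R1-ESC replicate 2 (2.38). In the fibroblast list the median was -0.20 without replicate 1 of 2-HPC-iPSC-18 (camera adjusted p = 0.22) and -1.23 without replicate 2 of 2-HPC-iPSC-18, with camera adjusted p from 2.0e-08 to 0.22 over its alternatives.

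In 3-APC-iPSC-3, Meg3 (ENSMUSG00000021268, chromosome 12, 110779211 to 110809936) averaged 134 ± 20.2 FPKM in the line and 412 ± 0.190 in R1-ESC (SD, n = 2), a log2 difference of -1.62 (SE 0.32, adjusted p = 0.0090), and Rian averaged 28.7 ± 7.21 FPKM against 71.8 ± 5.57 (SD, n = 2). For the Dlk1-Dio3 cluster 0 rose and 2 fell among 6 (0 and 4 adjusted over the list alone), with a median of -1.29 (camera adjusted p = 1.9e-04, 0.16 with an estimated correlation). Zfp42 averaged 80.5 ± 9.14 FPKM against 219.7 ± 8.35 (SD, n = 2). Of the primed-state genes 3 rose and 0 fell among 13 (3 and 0 adjusted over the list alone), with a median of 0.89 (camera adjusted p = 4.2e-04, 0.30 with an estimated correlation). Apoa2, Myl9 and Olig2 rose with log2 differences of 4.09, 2.40 and 2.07 (SE at most 0.43, adjusted p at most 0.0048), and Lcn2, Areg and Prg4, a joint lubricant gene, fell with log2 differences of -3.77, -3.02 and -2.74 (SE at most 0.39, adjusted p at most 6.5e-04). The loci high in fibroblasts stood at 12.7% and 16.5% of the 1-MEF level. With limma 364 loci were called, 95 higher and 269 lower. The count was 158 and 194 without replicates 1 and 2 of R1-ESC, 152 without replicate 1 of 3-APC-iPSC-3, and 76 (14 higher) in a limma fit on the compared groups alone, where of the genes named here only Apoa2, Lcn2, Myl9 and Prg4 stayed called. Meg3 lost its call without R1-ESC replicates 1 (-1.62) and 2 (-1.62) and 3-APC-iPSC-3 replicate 1 (-1.47). Rian lost its call without R1-ESC replicates 1 (-1.39) and 2 (-1.24) and 3-APC-iPSC-3 replicate 1 (-1.06). For the primed-state list the median was 0.51 without replicate 1 of 3-APC-iPSC-3 (camera adjusted p = 0.068), with camera adjusted p from 1.0e-06 to 0.068 over its alternatives. The share of higher calls was 26.1%, and it was 37.7% after quantile normalization.

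3-APC-iPSC-9 also had less Meg3 than R1-ESC, at 144 ± 36.0 FPKM against 412 ± 0.190 (SD, n = 2), and Rian averaged 32.5 ± 4.56 FPKM against 71.8 ± 5.57 (SD, n = 2), which did not pass. Of the Dlk1-Dio3 list 0 rose and 2 fell among 6 (0 and 4 adjusted over the list alone), with a median of -1.202 (camera adjusted p = 1.4e-04, 0.15 with an estimated correlation). Prss8, a membrane protease, and Cldn6, a claudin on the primed-state list, averaged 14.6 ± 1.24 FPKM against 2.84 ± 0.129 (SD, n = 2) and 59.7 ± 10.6 FPKM against 21.4 ± 1.53 (SD, n = 2). In the epithelial list, which holds neither, 1 rose and 0 fell among 16 (4 and 0 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 2.5e-09, 0.15 with an estimated correlation). Olig1, Olig2, Apoa2 and Dppa3 rose with log2 differences of 3.09, 2.67, 4.05 and 1.62 (SE at most 0.28, adjusted p at most 8.9e-04), and Zfp42 and Ier3 fell with log2 differences of -1.404 and -1.91 (SE at most 0.29, adjusted p at most 0.0017). For fibroblast and mesenchymal genes 2 rose and 4 fell among 26 (2 and 6 adjusted over the list alone), with a median of -0.74 (camera adjusted p = 3.0e-04, 0.49 with an estimated correlation), and the loci high in fibroblasts stood at 11.8% and 13.5% of the 1-MEF level. Altogether limma called 390 loci, 118 higher and 272 lower. The count was 173 and 206 without replicates 1 and 2 of R1-ESC, 229 without replicate 2 of 3-APC-iPSC-9, and 121 (22 higher) in a limma fit on the compared groups alone, where of the genes named here only Apoa2, Olig2, Prss8 and Zfp42 stayed called. Meg3 lost its call without R1-ESC replicates 1 (-1.53) and 2 (-1.53) and 3-APC-iPSC-9 replicate 2 (-1.28). Higher calls made up 30.3%, and 40.4% after quantile normalization.

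65 loci, 50 of them protein-coding, were called in the same direction in all 8 lines, 8 higher and 57 lower than in R1-ESC. Apoa2 was higher by 3.64 to 4.86 on the log2 scale over the lines, Olig1 by 2.14 to 3.19, Olig2 by 2.07 to 3.16 and the ribosomal protein gene Rpl34, which has many processed copies, by 1.298 to 1.57. Lower in every line were Areg (-3.61 to -2.54), Penk (-3.65 to -2.61), Prg4 (-2.85 to -2.18) and Zscan4c (-2.96 to -1.80), 1 of several near-identical Zscan4 copies, and Lcn2, which was listed at 0 in 2-APC-iPSC-32 and 3-APC-iPSC-9. These named genes were among the 28 loci that stayed called in all 8 lines without each library in turn, while the Y-linked Ddx3y (-2.39 to -1.03) was not, without replicate 2 of R1-ESC or replicate 1 of 1-MEF-iPSC-37. All 8 comparisons use the same R1-ESC libraries and so share their chance values. Unchanged groups with a shared reference gave a mean of 0 such loci in 20 simulations. Independent lists of these sizes would share 3.59e-14 higher and 2.81e-10 lower in all 8. The mean correlation of log2 differences between lines was 0.585 against 0.4997 simulated, the lowest 0.326 against a mean of 0.463, and the mean covariance 0.263 against 0.114. The count was 42 without replicate 2 of R1-ESC and 1 in fits on the compared groups alone. R1-ESC was represented by these libraries alone, so a peculiarity of them would appear in every line.

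Lines made from the same source were compared with each other, to measure the difference between clones. In 1-MEF-iPSC-42 against 1-MEF-iPSC-37, Dppa3 averaged 6.01 ± 1.75 FPKM against 57.5 ± 2.60 (SD, n = 2) and the ubiquitin ligase adaptor Klhl13 16.7 ± 8.29 FPKM against 123 ± 9.48 (SD, n = 2). Dnmt3b, the Nodal antagonist Lefty1, Grhl2 and Fgfr2 fell with log2 differences of -1.96, -1.76, -2.07 and -2.37 (SE at most 0.35, adjusted p at most 0.0036). Of the primed-state genes, Dnmt3b and Lefty1 among them, 0 rose and 5 fell among 13 (0 and 6 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.1e-05, 0.24 with an estimated correlation). The hypoxia-linked Ndrg1 averaged 91.7 ± 2.58 FPKM against 17.2 ± 1.66 (SD, n = 2), and the homeobox gene Rhox10 and the antiproliferative Btg2 rose with log2 differences of 2.40 and 1.60 (SE at most 0.23, adjusted p at most 0.0011). The glycolysis list as a whole was higher, where 1 rose and 0 fell among 17 (1 and 0 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 8.0e-10, 0.028 with an estimated correlation). Meg3 and Rian fell with log2 differences of -1.11 and -1.21 (SE at most 0.32, adjusted p at most 0.047). For fibroblast and mesenchymal genes 0 rose and 3 fell among 26 (0 and 8 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 3.1e-05, 0.61 with an estimated correlation); the loci high in fibroblasts stood at 13.2% and 6.30% of the 1-MEF level in 1-MEF-iPSC-42 and at 15.6% and 15.2% in 1-MEF-iPSC-37. Between these clones limma called 488 loci, 271 higher and 217 lower in 1-MEF-iPSC-42. The count was 249 and 235 without replicates 1 and 2 of 1-MEF-iPSC-37, 1633 without replicate 1 of 1-MEF-iPSC-42, and 0 in a limma fit on the compared groups alone (2453 at an unadjusted p under 0.05), where no gene named here was called. Meg3 lost its call without 1-MEF-iPSC-37 replicates 1 (-1.15) and 2 (-1.06) and 1-MEF-iPSC-42 replicate 2 (-0.67). Rian lost its call without 1-MEF-iPSC-37 replicates 1 (-1.26) and 2 (-1.17) and 1-MEF-iPSC-42 replicate 2 (-0.94). The fibroblast median was -1.60 without replicate 1 of 1-MEF-iPSC-42 and -0.25 without replicate 2 of 1-MEF-iPSC-42 (camera adjusted p = 0.63), with camera adjusted p from 2.8e-09 to 0.63 over its alternatives.

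2-APC-iPSC-4 had less Nanog than 2-APC-iPSC-32, at 144 ± 20.9 FPKM against 315 ± 0.166 (SD, n = 2). The Y-linked translation factor Eif2s3y averaged 20.03 ± 0.717 FPKM against 4.88 ± 0.408 (SD, n = 2). Among fibroblast and mesenchymal genes 0 rose and 0 fell among 26 (0 and 0 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 0.013, 0.77 with an estimated correlation), with 2-APC-iPSC-4 at 10.5% and 5.39% of the 1-MEF level over the loci high in fibroblasts and 2-APC-iPSC-32 at 5.06% and 4.80%. The pair gave 63 limma calls, 37 higher and 26 lower in 2-APC-iPSC-4, and 25 after quantile normalization. The count was 11 and 7 without replicates 1 and 2 of 2-APC-iPSC-32, 18 and 171 without replicates 1 and 2 of 2-APC-iPSC-4, and 33 (14 higher) in a limma fit on the compared groups alone, where no gene named here was called. Nanog lost its call without 2-APC-iPSC-32 replicates 1 (-1.13) and 2 (-1.13) and 2-APC-iPSC-4 replicate 1 (-0.98). In the fibroblast list the median was 0.09 without replicate 1 of 2-APC-iPSC-4 (camera adjusted p = 0.61, its direction lower) and 1.43 without replicate 2 of 2-APC-iPSC-4, with camera adjusted p from 2.0e-07 to 0.61 over its alternatives. The share of higher calls was 58.7%, and it was 44.0% after quantile normalization and 33.3% after median ratio scaling.

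Between the 2-HPC lines, the fibroblast and mesenchymal list was lower in 2-HPC-iPSC-18: 0 rose and 11 fell among 26 (0 and 19 adjusted over the list alone), with a median of -1.63 (camera adjusted p = 5.1e-16, 0.18 with an estimated correlation). The transcription factor Snai1, which represses epithelial genes, averaged 8.89 ± 0.204 FPKM against 48.9 ± 1.198 (SD, n = 2), and Atoh8 and Col4a1 fell with log2 differences of -2.60 and -1.69 (SE at most 0.33, adjusted p at most 0.0017). Of the Hox genes 0 rose and 6 fell among 32 (0 and 8 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 5.8e-17, 0.032 with an estimated correlation), with Hoxa9 at 0.981 ± 0.343 FPKM against 4.87 ± 0.520 (SD, n = 2). Pluripotency factors had a median log2 difference of 0.42 (camera adjusted p = 7.4e-06, 0.032 with an estimated correlation), with no member called. Aire, a regulator of thymic gene expression, Kirrel2 and Pfkp rose with log2 differences of 2.18, 1.498 and 1.10 (SE at most 0.36, adjusted p at most 0.0040). The test called 547 loci by limma, 106 higher and 441 lower, and 293 when loci 4-fold higher in 1-MEF cells than in the pluripotent groups were left out, a choice made after seeing the data. The count was 144 and 111 without replicates 1 and 2 of 2-HPC-iPSC-16, 58 and 850 without replicates 1 and 2 of 2-HPC-iPSC-18, and 46 (19 higher) in a limma fit on the compared groups alone, where of the genes named here only Snai1 stayed called.

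Between the 3-APC lines limma called 5 loci, 2 higher and 3 lower in 3-APC-iPSC-9, with 981 at an unadjusted p under 0.05. The rise that met the rule for named genes was that of Pdlim3, a protein of the muscle Z-disc, at 5.57 ± 0.866 FPKM against 1.93 ± 0.472 (SD, n = 2) with a log2 difference of 1.17 (SE 0.18, adjusted p = 0.026). The other 4, chosen here after their values were seen, were Oprm1, an opioid receptor gene (log2 difference -1.19, SE 0.12), the predicted gene Gm17416 (-1.35) and 2 small nucleolar RNA loci named SNORA17 (-3.14 and 3.34), whose reads are hard to place. The fibroblast list had a median log2 difference of -0.40 (camera adjusted p = 0.0020, 0.89 with an estimated correlation), with no member called. The count was 10 and 9 without replicates 1 and 2 of 3-APC-iPSC-3, 10 without replicate 1 of 3-APC-iPSC-9, and 31 (14 higher) in a limma fit on the compared groups alone, where Pdlim3 lost its call. Pdlim3 lost its call without 3-APC-iPSC-3 replicate 1 (1.002) and 3-APC-iPSC-9 replicates 1 (1.03) and 2 (1.301). For the fibroblast list the median was -0.11 without replicate 2 of 3-APC-iPSC-3 (camera adjusted p = 0.094), with camera adjusted p from 7.1e-04 to 0.094 over its alternatives. Higher calls made up 40.0%, and 25% after quantile normalization.

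Among source cells, 3-APC cells held less macrophage RNA than 2-APC cells: C1qb, a complement gene, averaged 6.54 ± 0.0479 FPKM against 137 ± 147 (SD, n = 2), at 241 and 33.0 in the 2 2-APC libraries, and of the macrophage genes 0 rose and 11 fell among 11 (0 and 11 adjusted over the list alone), with a median of -2.66 (camera adjusted p = 4.2e-13, 0.21 with an estimated correlation). Aldh1a2, which makes retinoic acid, averaged 1.10 ± 0.347 FPKM against 138 ± 6.49 (SD, n = 2), and the chaperone Clu, the chemokine Ccl6 and the muscle filament gene Des fell with log2 differences of -5.31, -5.18 and -4.60 (SE at most 0.76, adjusted p at most 6.8e-04). Tcf21, a regulator of visceral mesenchyme, averaged 33.6 ± 24.8 FPKM (SD, n = 2) in 2-APC cells and was listed at 0 in both 3-APC libraries, as were Hoxa10 and Hoxc10, at 14.9 and 11.8 FPKM in 2-APC cells. Of the Hox genes 0 rose and 6 fell among 32 (1 and 6 adjusted over the list alone), with a median of 0.03 and a mean of -0.31 (camera adjusted p = 0.29, 0.77 with an estimated correlation). Zic1, a neural crest and muscle regulator, and the imprinted Igf2 averaged 21.9 ± 0.635 FPKM against 1.33 ± 1.78 (SD, n = 2) and 71.7 ± 1.66 FPKM against 6.70 ± 6.31 (SD, n = 2). Of the endothelial genes 0 rose and 5 fell among 12 (0 and 8 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 1.1e-08, 0.22 with an estimated correlation). All Y-linked genes were lower, as 0 rose and 4 fell among 4 (0 and 4 adjusted over the list alone), with a median of -1.39 (camera adjusted p = 1.1e-08, 0.11 with an estimated correlation). Here 671 loci were called by limma, 118 higher and 553 lower. The count was 365 and 1856 without replicates 1 and 2 of 2-APC, 316 and 353 without replicates 1 and 2 of 3-APC, and 28 (16 higher) in a limma fit on the compared groups alone, where of the genes named here only Aldh1a2 and Clu stayed called. C1qb had a log2 difference of -2.17 without 2-APC replicate 1. The macrophage median was -1.31 and -4.47 without replicates 1 and 2 of 2-APC. In the endothelial list the median was -0.32 and -2.43 without replicates 1 and 2 of 2-APC.

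The blood and adipose progenitors were set side by side as 2-HPC minus 2-APC cells. S100a9 averaged 39208 ± 2947 FPKM against 0.330 ± 0.4664 (SD, n = 2), and the granule genes Mpo, Elane and Prtn3 rose with log2 differences of 11.39, 12.32 and 11.06 (SE at most 0.52, adjusted p at most 4.3e-11). The matrix genes Sparc and Col1a1 averaged 0.655 ± 0.162 FPKM against 5916 ± 1309 (SD, n = 2) and 0.126 ± 0.0471 FPKM against 4033 ± 1282 (SD, n = 2), and Timp1, Fbln2, Bgn and Col1a2 fell with log2 differences of -10.89, -10.53, -10.52 and -10.46 (SE at most 0.69, adjusted p at most 3.2e-09). Of the blood progenitor genes 16 rose and 1 fell among 21 (16 and 1 adjusted over the list alone), with a median of 3.34 (camera adjusted p = 1.2e-04, 0.15 with an estimated correlation), with the transcription factor Myb at 153 ± 2.39 FPKM against 0.106 ± 0.0910 (SD, n = 2). Of the erythroid genes 15 rose and 0 fell among 15 (15 and 0 adjusted over the list alone), with a median of 6.25 (camera adjusted p = 1.6e-13, 9.2e-04 with an estimated correlation). The Hox list was lower, as 0 rose and 23 fell among 32 (0 and 23 adjusted over the list alone), with a median of -1.73 (camera adjusted p = 2.1e-11, 0.063 with an estimated correlation). This comparison had 7035 limma calls, 3902 higher and 3133 lower, 5909 protein-coding. The median log2 difference of all loci moved by -0.13 with median ratio scaling.

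Compared with embryonic fibroblasts, 2-APC cells had less Igf2 at 6.70 ± 6.31 FPKM against 3375 ± 145 (SD, n = 2), less H19 at 83.7 ± 99.3 FPKM against 10000 ± 164 (SD, n = 2) and less Dlk1 at 9.16 ± 11.3 FPKM against 685 ± 7.69 (SD, n = 2). Of the paternally expressed imprinted genes 1 rose and 10 fell among 23 (1 and 10 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.0e-04, 0.12 with an estimated correlation). The muscle genes Mylpf and Tnni1 and the retinoic acid carrier Crabp1 fell with log2 differences of -7.51, -6.52 and -7.71 (SE at most 0.99, adjusted p at most 3.2e-05). The adipose gene Lpl averaged 239.7 ± 204 FPKM against 9.64 ± 0.453 (SD, n = 2), and of the adipose list 7 rose and 0 fell among 11 (7 and 0 adjusted over the list alone), with a median of 1.47 (camera adjusted p = 1.1e-04, 0.44 with an estimated correlation). Mfap5, Cck and Ccl6 rose with log2 differences of 4.26, 5.35 and 4.79 (SE at most 0.91, adjusted p at most 4.2e-04). The limma test gave 2263 calls, 843 higher and 1420 lower. The count was 740 (144 higher) in a limma fit on the compared groups alone, where of the genes named here only Cck, Igf2 and Mfap5 stayed called. For the adipose list the median was 0.52 and 2.38 without replicates 1 and 2 of 2-APC. The share of higher calls was 37.2%, and it was 53.4% after quantile normalization and 49.9% after median ratio scaling. The median log2 difference of all loci moved by 0.11 with quantile normalization and 0.11 with median ratio scaling.

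Treating each line as 1 sample and R1-ESC as another asks which differences exceed the spread between the 8 lines. R1-ESC, being 1 sample, is assumed to share that spread. Apoa2 averaged 32.5 ± 8.66 FPKM over the lines and 0.801 ± 0.0240 in R1-ESC (SD, n = 16 and 2), where n counts libraries, with a log2 difference of 4.18 (SE 0.34, adjusted p = 6.2e-04). Olig2 and Rpl34 rose with log2 differences of 2.56 and 1.402 (SE at most 0.35, adjusted p at most 0.013), and Lcn2, Penk, Areg and the ferroxidase Cp fell with log2 differences of -3.62, -3.003, -2.9997 and -2.87 (SE at most 0.39, adjusted p at most 0.010). Of the 2-cell-stage genes 0 rose and 1 fell among 5 (0 and 5 adjusted over the list alone), with a median of -2.14 (camera adjusted p = 9.8e-08, 0.31 with an estimated correlation). Of the macrophage genes 0 rose and 1 fell among 11 (0 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 2.0e-09, 0.26 with an estimated correlation). With 7 residual degrees of freedom limma called 99 loci, 10 higher and 89 lower. Without the filter on low values there were 183, and with that filter set on the compared libraries, a choice made after seeing the data, 57. The count was 157 without 1-MEF-iPSC-42 (the whole line).

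Lines of different origin were compared with 2 lines on each side, each line being 1 sample. From 2-APC to 3-APC lines the fibroblast list was higher in the median, as 0 rose and 0 fell among 26 (0 and 0 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 3.4e-06, 0.96 with an estimated correlation). The limma count was 10, 4 higher and 6 lower, and 1179 passed at an unadjusted p under 0.05. The 1 protein-coding locus among them, named after its values were seen, was the predicted gene Gm13151, with 63 bases of exon, listed at no more than 133 FPKM and above 0 in 2 of the 16 line libraries. None of the 10 had over 129 bases of exon, and 8 reached 0.1 FPKM in only 2 of the 16 line libraries. With the line as a random effect limma called 0 (1529 at an unadjusted p under 0.05). The count was 5 without replicate 1 of 2-APC-iPSC-4, 31 without 2-APC-iPSC-32 (the whole line), 33 without 3-APC-iPSC-3 (the whole line), 31 without 2-APC-iPSC-4 (the whole line) and 43 without 3-APC-iPSC-9 (the whole line).

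From 2-APC to 2-HPC lines, fibroblast and mesenchymal genes were again higher in the median, where 0 rose and 0 fell among 26 (0 and 0 adjusted over the list alone), with a median of 1.97 (camera adjusted p = 3.0e-10, 0.76 with an estimated correlation). For the Dlk1-Dio3 cluster 0 rose and 0 fell among 6 (3 and 0 adjusted over the list alone), with a median of 1.18 (camera adjusted p = 0.0033, 0.76 with an estimated correlation), and for Hox genes 0 rose and 0 fell among 32 (0 and 0 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 5.3e-07, 0.76 with an estimated correlation). Blood progenitor genes had 0 rises and 0 falls among 21 (0 and 0 adjusted over the list alone; camera adjusted p = 0.63). Here limma called 11 loci, 5 higher and 6 lower and 0 of them protein-coding, against 2408 loci at an unadjusted p under 0.05, and 18 with a pseudocount of 0.1. None of the 11 had over 122 bases of exon, and 9 reached 0.1 FPKM in only 2 of the 16 line libraries. The fit with the line as a random effect called 0 (3133 at an unadjusted p under 0.05). The count was 7 without replicate 2 of 2-HPC-iPSC-16, 6 without replicate 1 of 2-APC-iPSC-4, 32 without 2-APC-iPSC-32 (the whole line), 38 without 2-HPC-iPSC-16 (the whole line), 34 without 2-APC-iPSC-4 (the whole line) and 89 without 2-HPC-iPSC-18 (the whole line). The fibroblast median was 1.09 without the line 2-HPC-iPSC-16. In the Dlk1-Dio3 list the median was 0.94 without the line 2-APC-iPSC-4 (camera adjusted p = 0.12), with camera adjusted p from 2.3e-04 to 0.12 over its alternatives. For the Hox list the median was 0.11 without the line 2-HPC-iPSC-16 (camera adjusted p = 0.0504) and 0.80 without the line 2-HPC-iPSC-18, with camera adjusted p from 1.5e-14 to 0.0504 over its alternatives.

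Whether lines keep RNA of their source cell was asked with the loci that most distinguish 2-HPC from 2-APC cells. The 200 loci highest in 2-HPC over 2-APC cells, led by S100a9, had a median log2 difference of the 2-HPC from the 2-APC lines of 0 and a mean of -0.03, with 69 exactly 0 and 63 positive (limma's camera, unadjusted p = 0.29, 0 called singly). The 200 loci highest in 2-APC over 2-HPC cells, led by Sparc and Col1a1, were higher in the 2-HPC lines by a median of 1.52, with 188 positive and 0 called singly. For these, limma's camera gave p = 8.1e-28, and p = 0.14 with an estimated correlation of 0.532. The median was 0.88 without 2-HPC-iPSC-16 and 2.28 without 2-HPC-iPSC-18. The loci high in fibroblasts moved with this set: they stood at 29.1% and 29.0% of the 1-MEF level in 2-HPC-iPSC-16 and 10.05% and 15.5% in 2-HPC-iPSC-18, against 5.06% and 4.80% in 2-APC-iPSC-32 and 10.5% and 5.39% in 2-APC-iPSC-4. Both sets may hold the same loci in part, as their overlap was not counted.

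A trend over the first number of the names was fitted across the 8 lines. Number 1 has only fibroblast lines and number 3 only adipose lines, so the number and the source are partly the same. The primed-state list had the clearest slope: 0 rose and 0 fell among 13 (0 and 0 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 6.1e-09, 0.86 with an estimated correlation). The oxidative phosphorylation list gave a median log2 slope of -0.11 (camera adjusted p = 4.1e-07, 0.86 with an estimated correlation). No single locus passed: limma called 0, with 997 loci at an unadjusted p under 0.05, and the fit with the line as a random effect called 0 (1251 unadjusted). The primed-state median was 0.43 without the line 1-MEF-iPSC-42. In the oxidative phosphorylation list the median was -0.07 without the line 1-MEF-iPSC-42.

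Of the reprogramming factors, Pou5f1 averaged 1362 ± 31.7 FPKM (SD, n = 2) in R1-ESC and 1005 (2-HPC-iPSC-16) to 1545 (2-APC-iPSC-4) in the lines. Sox2 averaged 144 ± 0.998 and 86.9 (2-HPC-iPSC-16) to 136 (2-APC-iPSC-32), with 0 of the 8 lines called for either. Below the log2 difference of 1 that a call needs, adjusted p was 0.024 for Pou5f1 (-0.44) and 0.0012 for Sox2 (-0.72) in 2-HPC-iPSC-16 and 0.029 for Sox2 (-0.46) in 3-APC-iPSC-3. Klf4 averaged 134 ± 4.40 FPKM in R1-ESC and 65.8 (2-APC-iPSC-4) to 245 (1-MEF-iPSC-42) in the lines, below R1-ESC in all but 1-MEF-iPSC-42. It fell in 2-APC-iPSC-4 and 3-APC-iPSC-3 (log2 differences of -1.02 and -1.01, adjusted p at most 0.022). Both calls ended after median ratio scaling (-0.97 and -0.98), and the first also without any 1 of its 4 libraries. The second ended without either R1-ESC library, without replicate 1 of 3-APC-iPSC-3 (-0.63) or with the compared groups alone. Nanog averaged 188 ± 5.04 and 144 (2-APC-iPSC-4) to 315 (2-APC-iPSC-32), and Myc 47.8 ± 1.12 and 21.3 (1-MEF-iPSC-42) to 45.8 (2-HPC-iPSC-16), with no line called for either. Dnmt3b averaged 142 ± 9.38 and 44.1 (1-MEF-iPSC-42) to 289 (3-APC-iPSC-3), and fell in 1-MEF-iPSC-42.

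In the imprinted cluster, Meg3 averaged 412 ± 0.190 FPKM (SD, n = 2) in R1-ESC, 478 ± 20.9 in 1-MEF-iPSC-37, 575 ± 8.44 in 2-HPC-iPSC-16 and 489 ± 284 in 2-HPC-iPSC-18. It averaged 134 ± 20.2 in 3-APC-iPSC-3, 139 ± 26.2 in 2-APC-iPSC-4, 144 ± 36.0 in 3-APC-iPSC-9 and 178 ± 5.57 in 2-APC-iPSC-32. In 1-MEF-iPSC-42 it averaged 232 ± 97.9. Rian averaged 71.8 ± 5.57 FPKM in R1-ESC and 28.7 (3-APC-iPSC-3) to 104 (2-HPC-iPSC-16) in the lines, and Mirg 18.5 ± 0.215 and 7.03 (3-APC-iPSC-9) to 28.2 (2-HPC-iPSC-18), with no line called for Mirg. Among source cells Meg3 averaged 1139 ± 38.8 in 1-MEF, 526 ± 32.5 in 2-APC, 721 ± 35.7 in 3-APC and 1.13 ± 0.275 in 2-HPC cells. Strand was not stated, so reads of overlapping transcripts at this cluster cannot be told apart.

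**Figure D3:**
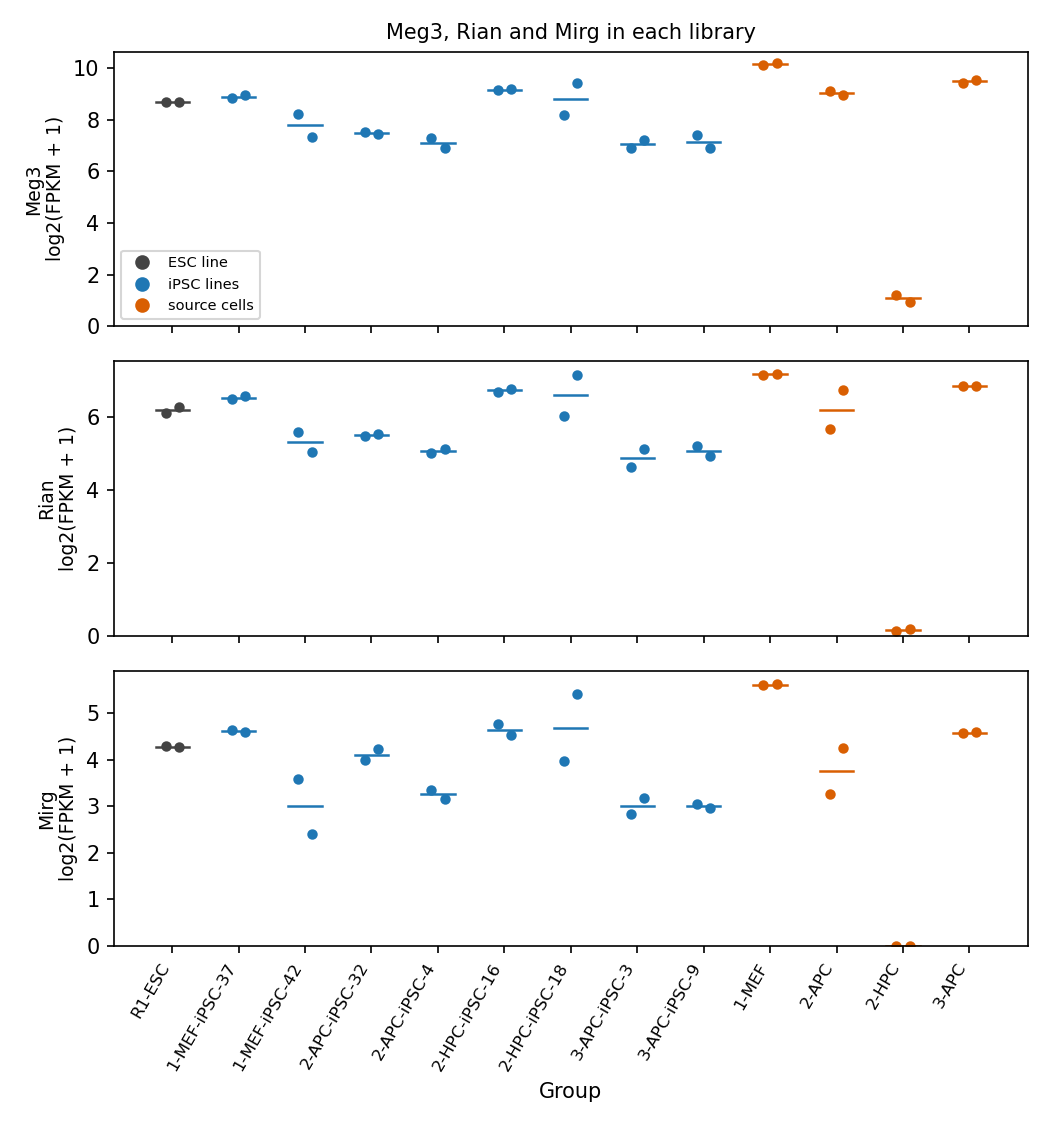
Meg3, Rian and Mirg as log2(FPKM + 1) in each of the 26 libraries, by group; points are libraries and lines are group means. Meg3 lies lower in both 2-APC and both 3-APC iPSC lines than in R1-ESC, and lowest in 2-HPC cells.

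The Y-linked Eif2s3y was at 60.9 and 63.6 FPKM in the 2 R1-ESC libraries, 21.5 and 28.1 in 1-MEF, 32.8 and 17.3 in 2-APC and 2.18 and 2.66 in 3-APC cells, and listed at 0 in both 2-HPC libraries. In the lines its group mean was 4.88 (2-APC-iPSC-32) to 44.5 (1-MEF-iPSC-42). Xist, the RNA that coats the inactive X chromosome, was at 227 and 242 FPKM in 2-HPC, 80.3 and 87.2 in 3-APC, 49.1 and 47.1 in 1-MEF, 28.3 and 42.1 in 2-APC and 12.4 and 11.6 in R1-ESC, and its mean was 2.80 (2-APC-iPSC-32) to 21.0 (2-HPC-iPSC-16) in the lines. Xist overlaps its antisense partner Tsix, and without strand their reads cannot be told apart.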

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

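Apart from the counts of other splits of the lines, the tests of explanations were chosen only after the result they measure was seen.

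Over the 8 iPSC lines, 58 values relative to R1-ESC were checked for a line standing apart, and 6 had 1 line whose gap to the nearest other line was too large for Dixon's test at the level of 0.05; chance gives about 1 in 20. In 1-MEF-iPSC-42 the log2 difference of Dnmt3b was -1.66 against 0.20 to 0.96 in the other lines, and that of Klf4 0.85 against -1.02 to -0.26. The mean log2 difference in that line was 0.34 against -0.02 to 0.14 for oxidative phosphorylation genes and 0.33 against -0.03 to 0.09 for replication-dependent histone genes, whose RNA mostly lacks the poly(A) tail that the selection needs. In 2-HPC-iPSC-16 the mean was 0.75 against -0.33 to 0.13 for Hox genes and -0.39 against -0.23 to -0.13 for the transcripts of the Rosa26 locus.

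For 5 lists, 1 line lay above R1-ESC and another below it. Each pair was picked among the lines for these signs, so a test between the 2 lines would be decided by the choice, and medians alone are given. Primed-state genes were higher in 3-APC-iPSC-3 than in 1-MEF-iPSC-42 by a median log2 difference of 1.94. Fibroblast and mesenchymal genes were higher in 2-HPC-iPSC-16 than in 2-APC-iPSC-32 by 3.29, and Hox genes by 0.85. Cell cycle genes were higher in 2-APC-iPSC-4 than in 2-HPC-iPSC-16 by 0.43, and glycolysis genes in 1-MEF-iPSC-42 than in 2-APC-iPSC-32 by 0.83.

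Genes of fibroblasts differed among the pluripotent lines. Scaling between libraries was argued against, since after median ratio scaling the loci high in fibroblasts still had a median log2 difference of 2.07 between 2-HPC-iPSC-16 and 2-APC-iPSC-32. RNA from fibroblast-type cells in the cultures, such as feeder cells, whose use is not given in the sources used here, may explain the pattern but was not shown to: the share of the loci moving 1 way between replicates was 75.4% to 86.2% in 1-MEF-iPSC-42, 2-APC-iPSC-4 and 2-HPC-iPSC-18, which were picked because their replicates differed, under the 90% set for such RNA, and 50.3% to 80.8% in the other lines. Cells that had left the pluripotent state cannot be told apart from it, as pluripotency factors had a median of -0.542 in 2-HPC-iPSC-16 minus 2-APC-iPSC-32 while mesoderm genes had -0.27. Carry-over from the source cell would raise 2-APC loci in the 2-APC lines, and the 200 loci highest in 2-APC over 2-HPC cells were higher in the 2-HPC lines instead, by a median of 1.52 (0.88 without 2-HPC-iPSC-16; limma's camera, p = 0.14 with an estimated correlation), but the loci high in fibroblasts moved with them, so carry-over stays open, and other effects of the source were not tested.

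Meg3 was lower than in R1-ESC by log2 differences of -1.62 in 3-APC-iPSC-3, -1.53 in 3-APC-iPSC-9, -1.58 in 2-APC-iPSC-4 and -1.202 in 2-APC-iPSC-32, and was at -0.90 in 1-MEF-iPSC-42, where it was not called. In both 3-APC lines less fibroblast-type RNA was argued against, since the loci high in fibroblasts lay at least 1.26 above Meg3, beyond their interquartile range, and scaling too, since Meg3 was at -1.55 or lower under both scalings. In 2-APC-iPSC-4 and 1-MEF-iPSC-42 the gaps were 0.704 and 0.273, within interquartile ranges of 1.14 and 1.12, and in 2-APC-iPSC-32 the gap was -0.11, so in these 3 lines less fibroblast-type RNA cannot be told apart from a change at the cluster. A trend over the first number of the names stays open: Meg3 had a slope of -0.62 with an exact permutation p of 0.167 (two-sided, 420 arrangements), and the number is partly the same as the source. A change of the imprint itself was not tested.

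Y-linked RNA was present in the 2-HPC iPSC lines, with Eif2s3y at 14.4 to 19.6 FPKM, but no Y-linked gene of the list exceeded 0.0334 FPKM in 2-HPC cells. Fibroblast-type RNA as its origin was argued against for Uty, at 235.7% of the 1-MEF level or more. It stays open for Eif2s3y, at 58.0% or more, as the loci high in fibroblasts below it were chosen as low in lines. Non-blood cells in the 2-HPC libraries stay open, since blood progenitor genes 3.34 above 2-APC cells (median log2) fit a mix too. A different sex of 2-HPC cells and the cells behind the lines stays open. Xist was highest in 2-HPC cells, but the sources give no sex. A bound of 0 for Y-linked RNA in 2-HPC cells was set first. Ddx3y passed it at 0.0334 and 0.0324 FPKM, and 0.1 was used after that was seen.

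Other splits of the 4 lines were counted for the comparisons of lines of different origin. For 3-APC against 2-APC lines, 2 of 3 splits gave at least 10 loci, with 12 as the highest other, and for 2-HPC against 2-APC lines 2 of 3 gave at least 11, with 16 as the highest other; these splits are too few for a share under 0.05.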

How the results depend on the processing

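The limits to protein-coding loci, to loci not high in 1-MEF cells and to loci filtered on the compared libraries, the alternatives of single gene lists and those of the loci called in all 8 lines were chosen after seeing the data. No called locus changed direction in any comparison of counts. Counts within 1.5 times the reported one were counted as kept, out of 23: 23 with median ratio scaling, 22 with quantile normalization, 22 without the filter, 19 with a pseudocount of 0.1 and 23 without loci of another status than OK. With the replicate number as a block, 19 of 19 were kept. For named genes 3005 outcomes kept their side of the threshold, 118 lost it and 2 gained it, with 70 of the losses in fits on the compared groups alone.

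A pseudocount of 0.1 moved the count against R1-ESC to 2007 (2-APC-iPSC-32) and 1095 (2-APC-iPSC-4), and in the others to 3 (3-APC sister lines) and 18 (2-HPC minus 2-APC lines), and enlarged the medians of lists with low values. Without the filter it was 183 for all lines minus R1-ESC, and quantile normalization gave 25 for 2-APC-iPSC-4 minus 2-APC-iPSC-32; the cause was not tested for these. Without a minimum difference, which by construction adds loci, counts moved against R1-ESC to 598 (1-MEF-iPSC-37), 3245 (2-APC-iPSC-32), 2293 (2-HPC-iPSC-16), 1013 (3-APC-iPSC-3), 2043 (1-MEF-iPSC-42), 2084 (2-APC-iPSC-4), 655 (2-HPC-iPSC-18) and 1013 (3-APC-iPSC-9), and in the others to 12293 (1-MEF lines minus cells), 13373 (2-APC lines minus cells), 13412 (2-HPC lines minus cells), 12660 (3-APC lines minus cells), 1540 (1-MEF sister lines), 261 (2-APC sister lines), 1593 (2-HPC sister lines), 1227 (3-APC minus 2-APC cells), 11891 (2-HPC minus 2-APC cells), 6034 (2-APC minus 1-MEF cells) and 190 (all lines minus R1-ESC), and 126 loci were called in all 8 lines. Fits on the compared groups alone, which have fewer libraries for the spread, moved them against R1-ESC to 440 (1-MEF-iPSC-37), 76 (3-APC-iPSC-3), 1 (1-MEF-iPSC-42), 81 (2-APC-iPSC-4), 93 (2-HPC-iPSC-18) and 121 (3-APC-iPSC-9), and in the others to 0 (1-MEF sister lines), 33 (2-APC sister lines), 46 (2-HPC sister lines), 31 (3-APC sister lines), 28 (3-APC minus 2-APC cells) and 740 (2-APC minus 1-MEF cells), where the 0 is limma's, with 2453 loci at an unadjusted p under 0.05, and 1 locus was called in all 8 lines.

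With the line as a random effect in limma, the counts of 3-APC minus 2-APC lines and of 2-HPC minus 2-APC lines were 0 and 0 (1529 and 3133 at an unadjusted p under 0.05), and with a replicate block added 0 and 0 (1494 and 3112). With protein-coding loci only they were 1 and 0 (2079 at an unadjusted p under 0.05 for the latter), and 3 between the 3-APC lines, as fewer loci were tested. Without loci 4-fold higher in 1-MEF cells, 2-HPC-iPSC-18 minus 2-HPC-iPSC-16 had 293, and with the filter on the compared libraries all lines minus R1-ESC had 57.

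Leaving out 1 library or line moved 43 of 134 counts for libraries and 9 of 24 for lines. Against R1-ESC the counts ran over 103 to 117 (1-MEF-iPSC-37), 373 to 455 (2-HPC-iPSC-16), 152 to 363 (3-APC-iPSC-3), 341 to 1733 (1-MEF-iPSC-42), 307 to 919 (2-APC-iPSC-4), 117 to 260 (2-HPC-iPSC-18) and 173 to 360 (3-APC-iPSC-9). In the others they ran over 235 to 1633 (1-MEF sister lines), 7 to 171 (2-APC sister lines), 58 to 850 (2-HPC sister lines), 6 to 10 (3-APC sister lines), 316 to 1856 (3-APC minus 2-APC cells), 83 to 157 (all lines minus R1-ESC), 5 to 43 (3-APC minus 2-APC lines) and 6 to 89 (2-HPC minus 2-APC lines), and loci called in all 8 lines over 42 to 65.

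The camera calls of named lists were the same in 61 of 61 cases with median ratio scaling, 61 with quantile normalization, 61 with a pseudocount of 0.1 and 390 of 398 with a library or line left out. The fibroblast list in 2-APC-iPSC-4 minus 2-APC-iPSC-32 turned to lower in camera without 2-APC-iPSC-4 replicate 1, though at a median of 0.0923 (limma's camera, adjusted p = 0.61, from 2.0e-07 to 0.61 over its alternatives) against 0.75, and 1.43 without its replicate 2; the cause was not tested. With an estimated correlation, 28 list calls stood in place of 335 of 897, and the set highest in 2-APC cells, at 1.52 in the 2-HPC over the 2-APC lines, lost its call, since that correlation enters the test. The median r with R1-ESC over the lines was 0.962, 0.945 with a pseudocount of 0.1 and 0.974 without the filter, beyond the replicate SD of 0.00167; values near 0 weigh more or number more there. The loci called between lines of different origin had at most 129 bases of exon, and whether depth limits them was not tested.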
